A study of Mus musculus with 78 samples.

How the data were processed

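The deposited values of the probe sets on 78 Affymetrix arrays were used as log2 RMA values, the unit the authors give for them. According to the submitters' processing notes the arrays were summarized by RMA, whose version is not given in the sources used here. The labels describe total RNA of mouse brain extracted with Trizol, and biotin-labelled by in vitro transcription. The values lie between 2.606 and 14.24, none is missing, and all columns were matched to a sample. Sorted columns differed by a median root mean square of 0.03424 log2 units within an age and 0.1565 between ages, as in values normalized within each age. Differences between ages are therefore given relative to the median gene, while calls and counts of genes are not shifted.

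Of the probe sets 34958 name 1 gene, 932 name several, 9211 are not listed with a gene and 64 are array controls. Only those with 1 gene were used. A gene was represented by its probe set with the highest mean over all 78 arrays, which left 18193 genes. A gene was tested where its highest group mean reached 5.253, the median of all values, which left 11743 genes at E14, 11779 at P0, 12296 at P14, 12864 in the fit of wild types and 13052 in the fit of all arrays. Gene names were brought to current symbols, and the assembly GRCm38.p6 was used only for names and for the neighbours of a gene.

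Tests used R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. Linear models were fitted per age with 1 mean per group, over the wild types for development and over all 78 arrays for interactions. Variances were moderated by empirical Bayes with a trend on the mean level. Adjusted p-values of genes are those of limma after Benjamini-Hochberg correction, and a gene was called at adjusted p under 0.05. Where 2 mixed wild types serve as controls, the p-value of a gene is the larger of its 2 p-values if both differences have the same sign, and 1 otherwise, and the change is the mean of both. The same rule joins both mixed backgrounds in the 2 steps of development. Groups with inbred background in their label were compared with the inbred wild type. Covariances between mutants were set beside those of unchanged groups simulated 100 times against the same controls.

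The named genes follow a rule: in each comparison the 8 called genes with the largest rise and the 8 with the largest fall whose arrays do not overlap between groups, 12 and 12 in the 2 steps of development in mixed backgrounds, and for each gene list up to 4 called members with the largest change. The 4 targeted genes are followed in every comparison, and unnamed or predicted genes are passed over. The text gives a selection of these genes. Sex-linked genes are given once, by group.

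Gene lists were written from general knowledge of brain cell types, regions and pathways. They are cell cycle, radial glia and neural progenitors, intermediate progenitors and newborn neurons, LIS1 complex and neuronal migration, deep-layer and upper-layer cortical neurons, GABAergic neurons, synapse and neurotransmission, axon guidance, myelin and oligodendrocytes, oligodendrocyte precursors, astrocytes, microglia, endothelium and mural cells, red blood cells, choroid plexus, and meninges and fibroblasts. Further lists are midbrain, hindbrain and spinal cord, cerebellum, cortex and hippocampus, striatum, hypothalamus and pituitary, immediate early genes, hypoxia and glycolysis, p53 targets and apoptosis, unfolded protein response and amino acid stress, sterol biosynthesis, and interferon response. These 28 lists were tested with camera of limma at an inter-gene correlation of 0.01, with an estimated correlation as an alternative. List members absent from the arrays or under another symbol were not analysed here.

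The comparisons, the named-gene rule, the filter, the lists and the main alternatives were set before the data were examined. The alternatives were no filter, a stricter filter at 7.627 log2 units (the 75th percentile), every probe set, all 78 arrays in 1 fit and quantile normalization over all arrays. Further ones were a block on the replicate number, each mixed wild type alone or their mean, the inbred wild type for Ndel1 ko/+ at P14, split controls for overlaps, and leaving out each array in turn. A further 5 alternatives were chosen after seeing the data: a covariate for the region score at E14, leaving out the 6 arrays of low region score, leaving out the 2 arrays that keep Ywhae, the inbred wild type for mix-labelled Ndel1 ko/+, and list tests against the wild type on the same side of the first component.

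The procedure was tested on simulated data with 10 draws of 200 changed genes per comparison. At a 1.5-fold change it called 51.7% of them in Lis1 ko/cko at P0, 53.3% at P14 and 56.6% at E14, 73.8% in the Ndel1 dose at P0, 73.8% in inbred 14-3-3 epsilon ko/ko and 22.7% in the interaction of Lis1 ko/cko with age. At a 2-fold change these were 89.9%, 87.7%, 87.1%, 97%, 95.9% and 67.7%, and the false calls were 1.39%, 1.81%, 1.1%, 4.79%, 4.77% and 1.53% of all calls. A list shifted by 0.50 log2 units was called in 10 of 10 draws, but in 0 of 10 in the interaction. These rates are of simulated data only. Other splits of the real arrays called up to 5602 genes (Ndel1 ko/+ at P14), so false calls there were not measured.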

Results

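Gene expression in mouse brain was measured on 78 Affymetrix arrays, 1 per RNA sample. The samples were taken at embryonic day 14 (E14), on the day of birth (P0) and at postnatal day 14 (P14), and fall into 26 groups of 3, which the labels call biological replicates. The mutants carry changes in Pafah1b1, Ndel1, Ywhae or Dcx. Pafah1b1 encodes LIS1, a regulator of the motor protein dynein, and the product of Ndel1 binds LIS1 and dynein. Ywhae encodes 14-3-3 epsilon, a protein that binds phosphorylated NDEL1. Dcx encodes doublecortin, a microtubule protein of migrating neurons. According to the labels, Lis1 and Ndel1 mutants were either heterozygous (ko/+) or carried a conditional over a null allele (ko/cko), Dcx mutants were ko/Y and 14-3-3 epsilon mutants were ko/ko. Wild-type brains came from mixed background A, mixed background B and an inbred background. The question the series sets is whether mutants of members of this complex change gene expression alike or each in its own way. A mutant gene was called where it passed against both mixed wild types. A change is the mean log2 difference from them ± the larger of the 2 standard errors, with n = 3 arrays in every group, and the number of arrays limits its precision. P-values measure the spread between samples labelled biological replicates. Counts adjusted over the list alone are printed where they differ from those over all genes, and in this section are equal where not given.

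The targeted genes were examined first. Dcx averaged 4.58 ± 0.26 (log2 value, mean ± SD, n = 3) in Dcx ko/Y at E14 against 12.06 ± 0.06 in mixed A and 12.07 ± 0.05 in mixed B. At P0 it averaged 4.30 ± 0.19 against 11.84 ± 0.28 and 12.03 ± 0.08. Ywhae averaged 9.83 ± 0.18 in inbred 14-3-3 epsilon ko/ko at P0 against 12.75 ± 0.05 in inbred wild type. At E14 the 3 arrays labelled 14-3-3 epsilon ko/ko held Ywhae at 12.68, 12.92 and 9.97, against means of 13.06 ± 0.03 in mixed A and 12.99 ± 0.02 in mixed B. The libraries labelled 14-3-3 epsilon ko/ko replicates 1 and 2 thus go against their label. Ndel1 averaged 9.45 ± 0.02 in Ndel1 ko/+ and 9.82 ± 0.04 in Ndel1 ko/cko at E14, against 9.90 ± 0.06 and 9.91 ± 0.02 in mixed A and B. At P0 these were 9.33 ± 0.07 and 9.56 ± 0.06 against 9.89 ± 0.11 and 9.74 ± 0.13, and at P14 10.01 ± 0.03 and 10.00 ± 0.13 against 10.39 ± 0.06 and 10.32 ± 0.03. The libraries labelled Ndel1 ko/+ in the inbred background at P0 (10.06 ± 0.17 against 9.91 ± 0.09 in inbred wild type) and the libraries labelled Ndel1 ko/+ with mix in their label at P14 (10.55 ± 0.04) held no lower Ndel1 than wild type. The libraries labelled Ndel1 ko/cko at E14 go against their label too, with differences of -0.08 ± 0.07 from mixed A and -0.09 ± 0.07 from mixed B and a level above that of Ndel1 ko/+.

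Pafah1b1 averaged 10.07 ± 0.09 in Lis1 ko/+ and 9.84 ± 0.17 in Lis1 ko/cko at E14 against 10.38 ± 0.14 in mixed A and 10.43 ± 0.01 in mixed B. At P0 it averaged 10.01 ± 0.15 and 10.08 ± 0.06 against 10.51 ± 0.06 and 9.95 ± 0.15, and at P14 10.21 ± 0.10 and 10.36 ± 0.06 against 10.85 ± 0.03 and 10.48 ± 0.01. It was called in no Lis1 mutant group: the adjusted p (limma) was 0.173 in Lis1 ko/cko at E14, 1 at P0 and 0.511 at P14. The 5 Pafah1b1 probe sets did not move alike. The probe set with the clearest difference, chosen after its values were seen, gave -0.52 ± 0.07 against mixed A and -0.53 ± 0.07 against mixed B in Lis1 ko/+ at P0, and -0.55 ± 0.07 against each in Lis1 ko/cko. Where the probe sets lie relative to the deleted parts is not given in the sources used here, and a probe set outside a deleted part checks nothing.

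**Figure D1:**
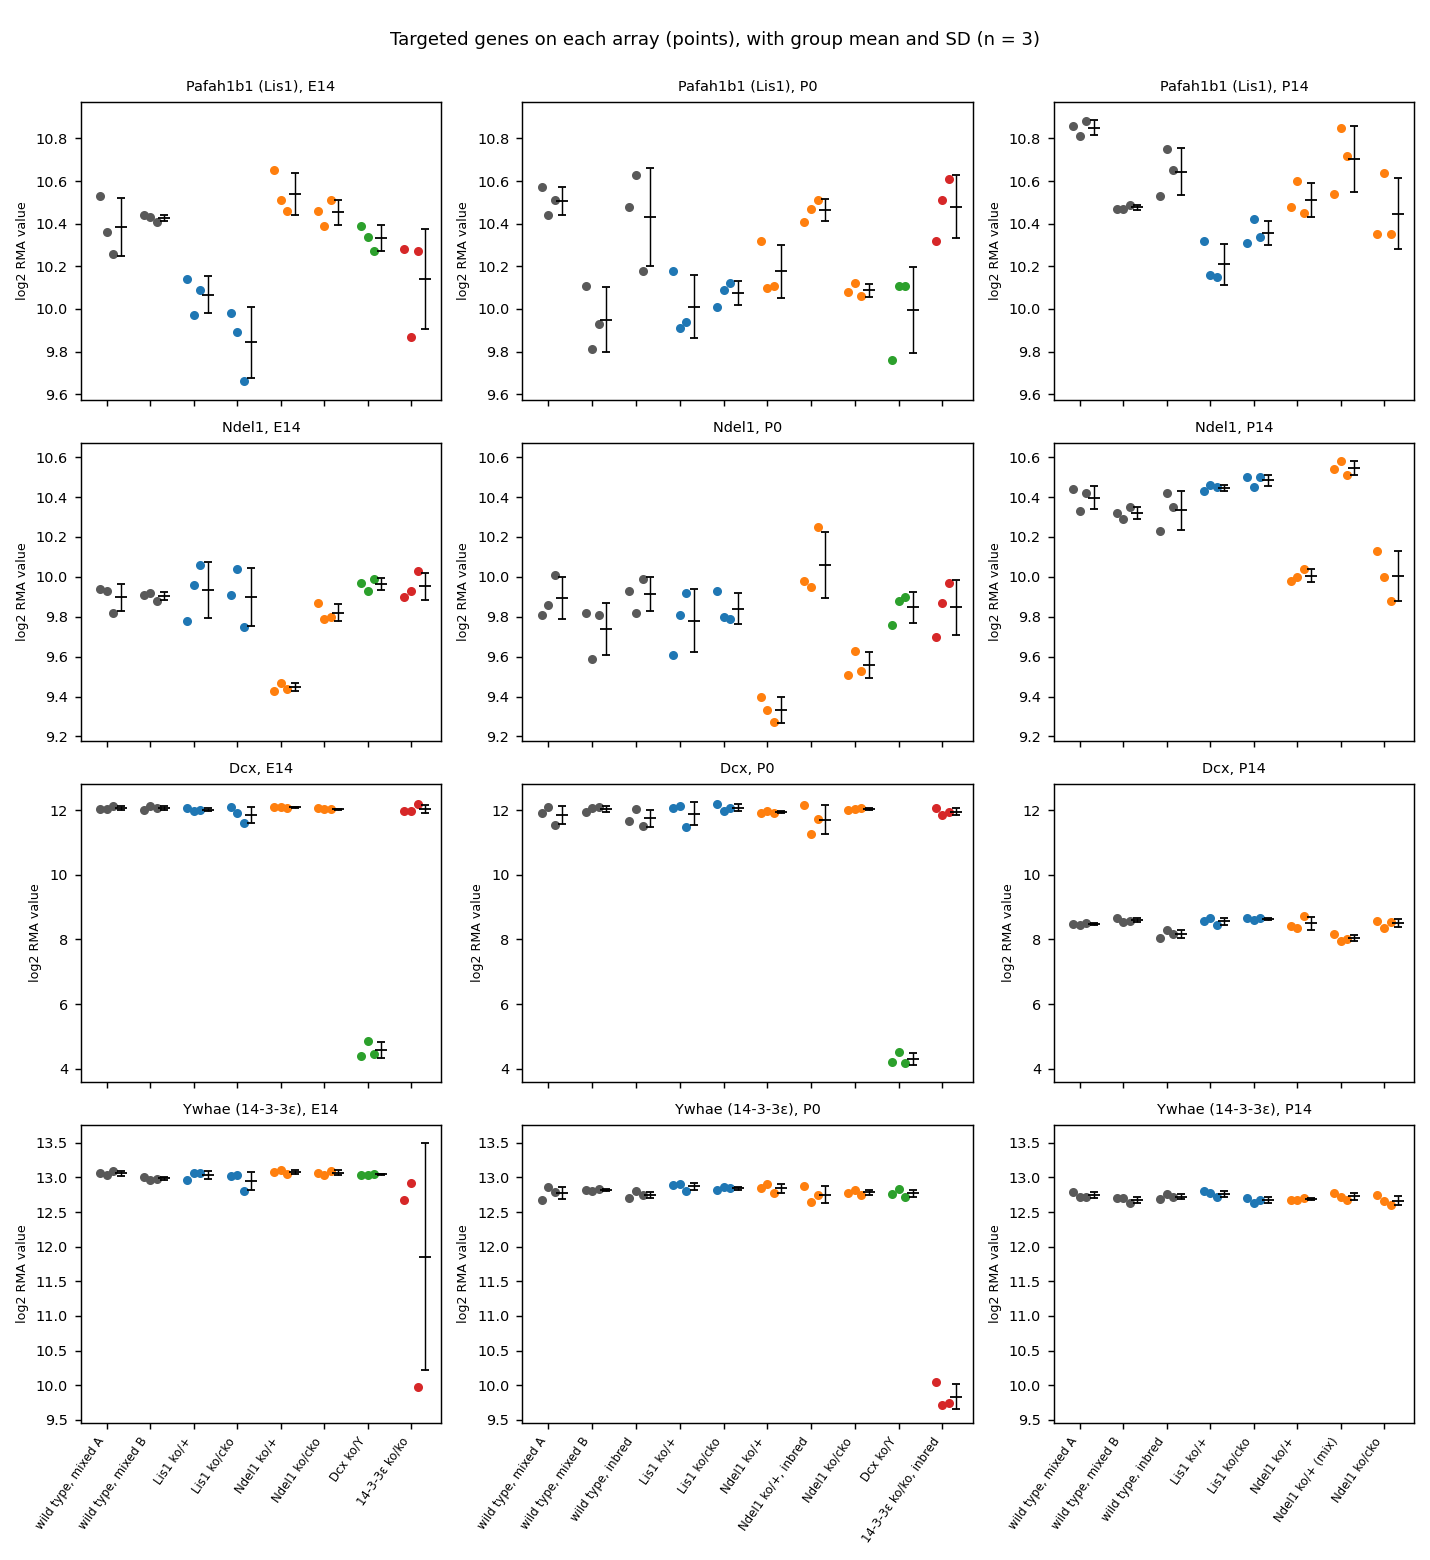
Log2 RMA value of the targeted genes on each array (points) by group and age, with group mean and SD (n = 3). Dcx averaged 4.30 ± 0.19 in Dcx ko/Y at P0, and 2 of the 3 arrays labelled 14-3-3 epsilon ko/ko at E14 held Ywhae at 12.68 and 12.92, near wild type.

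Sex-linked genes also differed between groups. Xist, the RNA that silences the inactive X chromosome, was between 11.91 and 12.02 log2 units in all 3 Ndel1 ko/cko arrays at E14, and Uty, a Y-linked gene, was between 3.98 and 4.37 there. Xist was also above 8 in 1 array of mixed B at E14, in 1 Ndel1 ko/cko array at P0 (11.54) and in the library labelled Dcx ko/Y replicate 2 at P0 (11.27), which goes against a ko/Y label.

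At P0 and P14 the arrays lay on 2 sides of the first principal component, which held 39.36% of the variance at P0 and 57.62% at P14. Mixed B, Ndel1 ko/+, Ndel1 ko/cko and Dcx ko/Y were on 1 side, while mixed A, both Lis1 groups, the groups with inbred in their label and mix-labelled Ndel1 ko/+ were on the other, and 0 of the 18 groups had arrays on both. At P0 the difference between 3' and 5' actin probe sets, a sign of RNA integrity, was 0.274 to 0.449 log2 units on the side of mixed B and 0.122 to 0.214 on the side of mixed A. At P14 it overlapped, with 0.627 to 0.717 on the side of mixed B and 0.497 to 0.956 on that of mixed A. At E14 the first component (48.45%) followed the level of midbrain, hindbrain and spinal cord genes. The 6 lowest of 24 arrays (mixed A replicates 2 and 3, Lis1 ko/+ replicate 1, Lis1 ko/cko replicates 1 and 3 and the library labelled 14-3-3 epsilon ko/ko replicate 2) had a mean level of this list between 4.72 and 4.85. Over all measured members of each list, more than enter that score, the mean of midbrain, hindbrain and spinal cord genes differed by -1.21 between these 6 arrays and the others, that of meninges and fibroblasts by -1.54 and that of choroid plexus by -1.09, whereas cell cycle genes were 0.53 and cortex and hippocampus genes 0.50 higher. These splits of the arrays were seen in the data and are not groups of the study.

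**Figure D2:**
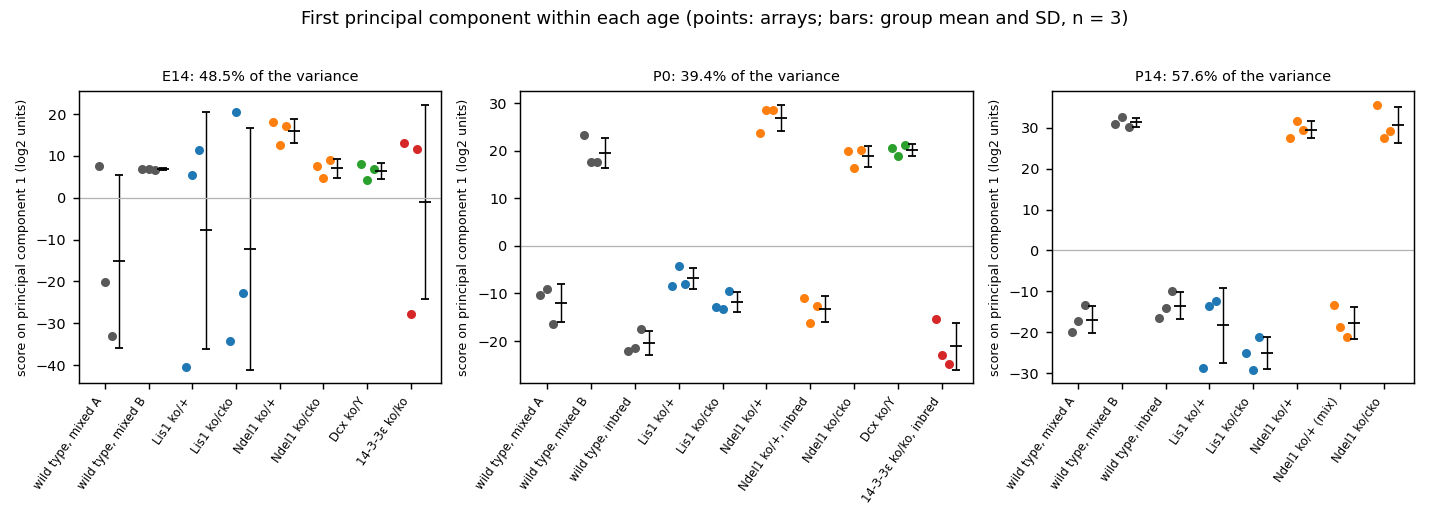
Score of each array (points, log2 units) on the first principal component within each age, by group, with group mean and SD (n = 3). At P0 and P14 each group lies on 1 side of 0, at P0 for example mixed A between -16.5 and -9.1 and mixed B between 17.6 and 23.2.

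**Figure D3:**
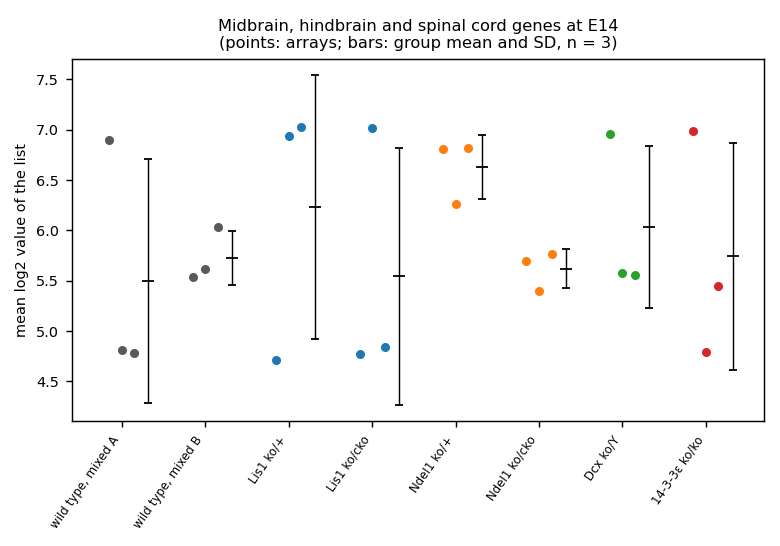
Mean log2 value of midbrain, hindbrain and spinal cord genes on each array (points) at E14 by group, with group mean and SD (n = 3). The 6 lowest arrays lie between 4.72 and 4.85 and belong to 4 groups.

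Wild-type brain was compared between E14 and P0 in both mixed backgrounds. Changes are relative to the median gene, which shifted by -0.19 log2 units, but calls and counts are not. All 38 tested cell cycle genes fell (median -2.16, camera adjusted p = 7.59e-18, and adjusted p = 0.0571 with an estimated correlation), such as Bub1, a spindle checkpoint kinase (-3.44 ± 0.13), Kif20a (-3.10 ± 0.15) and Cdc6 (-3.02 ± 0.14). All 16 genes of intermediate progenitors and newborn neurons fell (median -1.55, camera adjusted p = 3.47e-07, and adjusted p = 0.0263 with an estimated correlation). The proneural factor Neurog2 was at -4.23 ± 0.20, Nhlh1 at -3.40 ± 0.12 and Eomes at -2.88 ± 0.23. Of 22 radial glia genes 17 fell and 2 rose (camera adjusted p = 0.000775, and adjusted p = 0.237 with an estimated correlation). Sox3 was at -2.57 ± 0.18 and Pax6 at -1.81 ± 0.13. Of 28 synapse genes 23 rose and 1 fell, 24 and 1 adjusted over the list alone (camera adjusted p = 1.64e-10, and adjusted p = 0.0263 with an estimated correlation). Neurogranin, Nrgn, was at 4.66 ± 0.14 and Camk2b at 2.18 ± 0.11. Of 17 astrocyte genes 11 rose and 1 fell (camera adjusted p = 3.47e-07, and adjusted p = 0.0263 with an estimated correlation), such as the water channel Aqp4 (4.53 ± 0.18) and Apoe (2.58 ± 0.21). The remaining calls were upper-layer neurons, where 6 of 13 rose, 5 adjusted over the list alone (camera adjusted p = 0.0161). Further calls were immediate early genes, where 8 of 16 rose and 4 fell (camera adjusted p = 0.0493). Both had adjusted p = 0.493 with an estimated correlation. The last was interferon response, where 4 of 12 rose (camera adjusted p = 0.0272, and adjusted p = 0.376 with an estimated correlation). Among single genes the embryonic globins Hbb-y (-7.32 ± 0.21) and Hba-x (-4.66 ± 0.17) fell, while Thy1 (3.85 ± 0.18), Mlip (3.73 ± 0.11), Ramp1 (3.66 ± 0.11) and the deiodinase Dio2 (3.58 ± 0.11) rose.

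The other 20 lists were not called between E14 and P0 (camera adjusted p of 0.0857 or more). In the LIS1 list 5 of 40 rose and 12 fell, with Nde1 at -2.19 ± 0.10 and Dync1i1 at 2.16 ± 0.15. In deep-layer neurons 4 of 13 rose and 3 fell, in GABAergic neurons 3 of 17 rose and 4 fell, in axon guidance 7 of 31 rose and 9 fell, 7 and 10 adjusted over the list alone. In myelin 3 of 16 rose and 1 fell and in oligodendrocyte precursors 3 of 7 rose and 1 fell. In microglia 3 of 14 rose and 0 fell, in endothelium 1 of 17 rose and 2 fell, 1 and 1 adjusted over the list alone. In red blood cells 0 of 7 rose and 4 fell, in choroid plexus 1 of 12 rose and 3 fell and in meninges 3 of 15 rose and 0 fell. In midbrain, hindbrain and spinal cord 0 of 11 rose and 6 fell, in cerebellum 2 of 10 rose and 6 fell. In cortex and hippocampus 3 of 11 rose and 3 fell, in striatum 7 of 12 rose and 3 fell and in hypothalamus and pituitary 3 of 10 rose and 2 fell. In hypoxia 3 of 18 rose and 7 fell, 4 and 7 adjusted over the list alone, and in p53 targets 4 of 14 rose and 5 fell. In the unfolded protein response 3 of 17 rose and 11 fell and in sterol biosynthesis 0 of 16 rose and 3 fell, 0 and 2 adjusted over the list alone. In all, 6411 of 12864 genes were called, 1903 higher and 4508 lower at P0. With quantile normalization over all arrays the split was 3339 higher and 2540 lower. The low region score of mixed A replicates 2 and 3 at E14 stands beside the region, meninges and cell cycle counts.

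From P0 to P14, with the median gene at 0.13 log2 units, all 16 myelin genes rose (median 3.06, camera adjusted p = 3.29e-09, and adjusted p = 0.032 with an estimated correlation), such as Mobp (5.27 ± 0.13), Mog (4.84 ± 0.12) and Mag (4.71 ± 0.15). Of 17 astrocyte genes 16 rose (camera adjusted p = 7.17e-07, and adjusted p = 0.032 with an estimated correlation). S100b was at 4.95 ± 0.13 and Ntsr2 at 4.48 ± 0.13. Of 28 synapse genes 24 rose and 2 fell (camera adjusted p = 3.38e-06, and adjusted p = 0.122 with an estimated correlation). The vesicular glutamate transporter Slc17a7 was at 4.34 ± 0.21 and Camk2a at 3.55 ± 0.17. Of 14 microglia genes 13 rose (camera adjusted p = 0.00352, and adjusted p = 0.484 with an estimated correlation). P2ry12 was at 3.11 ± 0.30. Of 16 immediate early genes 11 rose and 1 fell (camera adjusted p = 0.00949, and adjusted p = 0.418 with an estimated correlation). Arc was at 3.95 ± 0.20. Of 38 cell cycle genes 32 fell and 3 rose, 34 and 3 adjusted over the list alone (camera adjusted p = 2.97e-11, and adjusted p = 0.137 with an estimated correlation). Of 31 axon guidance genes 20 fell and 4 rose, 20 and 5 adjusted over the list alone (camera adjusted p = 0.00042, and adjusted p = 0.137 with an estimated correlation). Cntn2 was at -2.91 ± 0.19. In the LIS1 list 18 of 40 fell and 8 rose (camera adjusted p = 0.0139, and adjusted p = 0.122 with an estimated correlation). Dcx was at -3.54 ± 0.11, Pafah1b3 at -3.08 ± 0.09 and Tubb3 at -1.73 ± 0.07. Radial glia genes (10 of 22 fell and 4 rose, camera adjusted p = 0.0139, and adjusted p = 0.418 with an estimated correlation) and intermediate progenitor genes (8 of 16 fell and 2 rose, camera adjusted p = 0.0465, and adjusted p = 0.448 with an estimated correlation) were also called. Among single genes the neuropeptide Vip (6.01 ± 0.18) and the link protein Hapln1 (5.22 ± 0.12) rose, and B3gnt5 (-4.67 ± 0.14), Isl1 (-4.41 ± 0.23), Draxin (-4.21 ± 0.14), the polysialyltransferase St8sia2 (-4.04 ± 0.13) and Sox11 (-3.97 ± 0.13) fell. In all, 7256 genes were called, 4408 higher and 2848 lower at P14.

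In the inbred wild type 9225 genes were called between P0 and P14, 4882 higher and 4343 lower. With the stricter filter these were 3097 and 3391. Changes are again relative to the median gene (0.04). Mobp (6.25 ± 0.13), Mag (5.81 ± 0.15), Vip (5.72 ± 0.18) and S100b (5.50 ± 0.13) rose, and B3gnt5 (-4.97 ± 0.14), Trim67 (-4.41 ± 0.14) and Dcx (-3.63 ± 0.11) fell. All 16 myelin genes rose (camera adjusted p = 3.98e-10), as did 16 of 17 astrocyte genes (camera adjusted p = 5.25e-08). Both lists had adjusted p = 0.0168 with an estimated correlation. Of 13 genes of deep-layer neurons 9 fell and 1 rose (camera adjusted p = 0.04, and adjusted p = 0.471 with an estimated correlation). Of 16 genes of sterol biosynthesis 9 fell and 1 rose (camera adjusted p = 0.0349, and adjusted p = 0.671 with an estimated correlation). These 2 lists were not called in the mixed brains, but the difference was not tested.

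**Figure D4:**
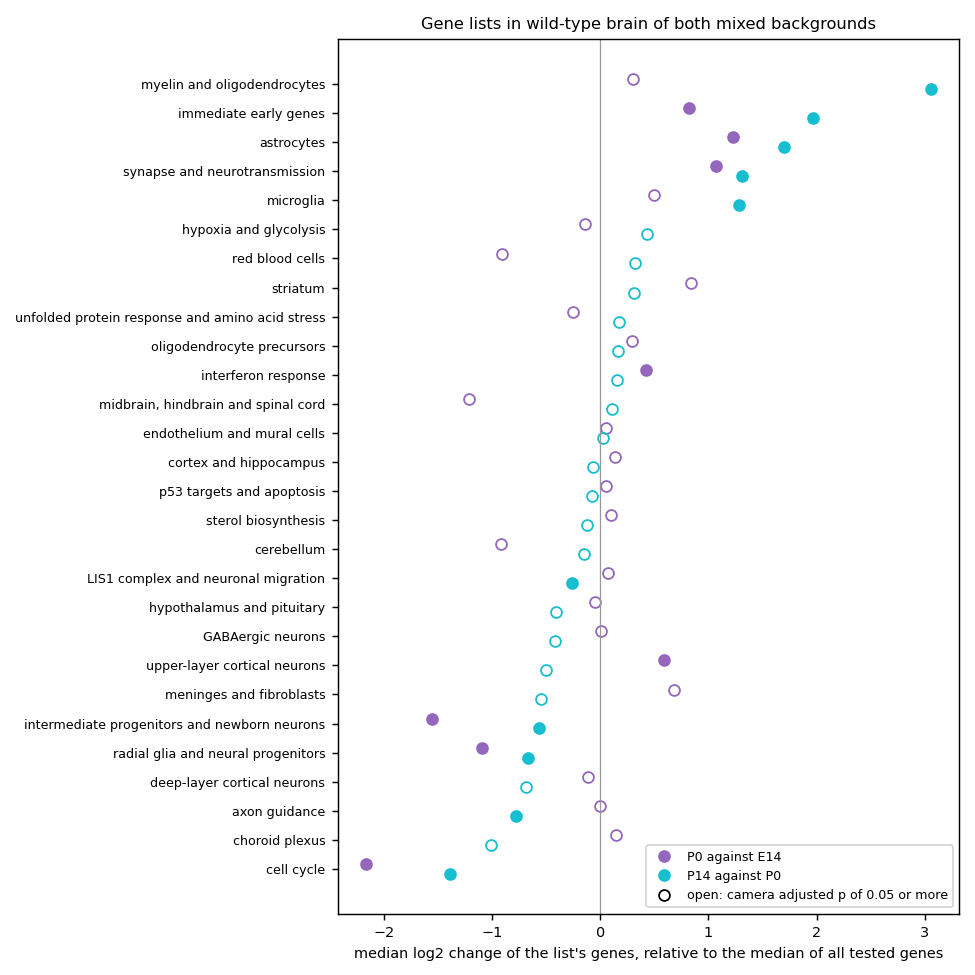
Median log2 change of each gene list in wild-type brain of both mixed backgrounds, relative to the median of all tested genes, for both steps of development (filled points: camera adjusted p under 0.05, open points: 0.05 or more). Cell cycle genes had a median of -2.16 from E14 to P0 and -1.39 from P0 to P14, and myelin genes 0.30 and 3.06.

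The wild types themselves differed. Between mixed A and mixed B 8 genes were called at E14 (5 higher in mixed A), among them Rmst (-2.45 ± 0.44) and Zfp33b (-1.28 ± 0.17). In leave-one-out runs this count was 46, 4 and 3 without mixed A replicates 1, 2 and 3 and 2, 3 and 1 without mixed B replicates 1, 2 and 3, and it was 14 without the 6 arrays of low region score, an alternative chosen after seeing the data. At P0 3386 genes were called, 2131 higher in mixed A, with Nipbl at 1.55 ± 0.15, Csnk2a1 at 1.36 ± 0.12, Zfp612 at -2.71 ± 0.17 and Rad1 at -2.20 ± 0.17. The count was 2232 without mixed B replicate 1. At P0 GABAergic genes were lower in mixed A (5 of 14, camera adjusted p = 0.0332, and adjusted p = 0.931 with an estimated correlation). Sp8 was at -1.14 ± 0.18, Dlx2 at -0.96 ± 0.13 and Gad2 at -0.85 ± 0.19. At P14 6478 genes were called, 4605 higher in mixed A, among them Tmem267 (3.21 ± 0.33), Drd2 (1.75 ± 0.29) and Mag (1.13 ± 0.15), while Stk25 (-2.76 ± 0.17) and Sox8 (-2.22 ± 0.19) were lower. The inbred wild type differed from both mixed wild types in 118 genes at P0 (88 higher) and 30 at P14 (5 higher, and 3605 of 5978 against mixed B alone), with B3galt1 lower at both ages (-1.31 ± 0.24 and -1.99 ± 0.31), Rpgrip1 lower at P0 (-1.37 ± 0.19) and Pcdhb9 lower at P14 (-2.47 ± 0.47). The count at P0 was 7 and 48 without inbred wild type replicates 2 and 3, and 180, 31 and 58 without mixed A replicates 1, 2 and 3. It was 57, 65 and 53 without mixed B replicates 1, 2 and 3. That at P14 was 0, 19 and 17 without inbred wild type replicates 1, 2 and 3, and 12, 8 and 0 without mixed A replicates 1, 2 and 3. It was 12 and 10 without mixed B replicates 1 and 3.

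At E14 few genes differed between mutants and both wild types. In Ndel1 ko/+ 4 genes were called: Rpgrip1, a protein of the photoreceptor cilium (3.46 ± 0.11), and Cldnd1 (0.59 ± 0.07) rose, and Tmem267 (-3.44 ± 0.46) and Ndel1 (-0.46 ± 0.07, adjusted p = 0.00952 by limma) fell. The count was 2 and 2 without Ndel1 ko/+ replicates 1 and 2 and 2 without mixed B replicate 1, and Ndel1 lost its call in 7 of the 9 runs that left out 1 array. In Dcx ko/Y 5 genes were called: Dcx (-7.49 ± 0.11, a lower bound on the loss, since its mean in the mutant was under the filter of 5.253) fell, and the class I histocompatibility genes H2-D1 (1.18 ± 0.16) and H2-K1 (1.05 ± 0.15), Rabl2 (0.82 ± 0.11) and Rpgrip1 (0.68 ± 0.11) rose. The count was 2 without Dcx ko/Y replicate 3. With limma 0 genes were called in Lis1 ko/+ (42 at unadjusted p under 0.05), Lis1 ko/cko (838), the group labelled Ndel1 ko/cko (66), whose Ndel1 goes against the label and whose 3 arrays hold Xist, and the group labelled 14-3-3 epsilon ko/ko (65), of which 2 libraries go against the label. In Lis1 ko/cko 418 genes were called without the 6 arrays of low region score, an alternative chosen after seeing the data that leaves 1 array each of Lis1 ko/cko and mixed A, assumed to vary like the other groups. Leaving out 1 array gave 382 without Lis1 ko/cko replicate 1 and 1 without mixed A replicate 2 in Lis1 ko/cko, 1 without Lis1 ko/+ replicate 1 in Lis1 ko/+ and 5 without mixed B replicate 1 in Ndel1 ko/cko. Without the 2 libraries that keep Ywhae, 1 gene was called in the group labelled 14-3-3 epsilon ko/ko.

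At E14 5 lists were called in Ndel1 ko/+ and 0 in the other mutant groups. With 0 members called in each, cell cycle genes (median -0.40, camera adjusted p = 2.72e-05, and adjusted p = 1 with an estimated correlation) and intermediate progenitor genes (-0.35, camera adjusted p = 0.00892) were lower. Genes of midbrain, hindbrain and spinal cord (0.78, camera adjusted p = 0.0396), microglia (0.35, 0.015) and astrocytes (0.20, 0.0396) were higher, and for each of these 4 lists adjusted p = 1 with an estimated correlation. All 3 Ndel1 ko/+ arrays had a region score above 5, while 2 of the 3 mixed A arrays had a low one.

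At P0 39 genes were called in Lis1 ko/cko, 3 higher and 36 lower, and against mixed B alone 2073 higher and 1789 lower. Of 11 striatum genes 3 fell, 4 adjusted over the list alone: Penk, which encodes enkephalin (-0.94 ± 0.18), Ebf1 (-0.78 ± 0.13) and Rarb (-0.77 ± 0.15). This 1 list was called (camera adjusted p = 0.0174, and adjusted p = 0.213 with an estimated correlation). Against mixed A alone, the wild type on the same side of the first component, 50 genes were higher and 228 lower. For the striatum list adjusted p = 0.0245 with an estimated correlation there, an alternative chosen after seeing the data. The microglial receptor P2ry12 (-1.56 ± 0.25), Nxph2 (-1.39 ± 0.17), Pla2g7 (-0.97 ± 0.17) and Rpgrip1 (-0.93 ± 0.19) fell, and Miip (0.72 ± 0.12), the kinesin Kif1a (0.69 ± 0.10) and Dop1b (0.55 ± 0.09) rose. In leave-one-out runs the count was 19, 1 and 15 without Lis1 ko/cko replicates 1, 2 and 3, and 59, 23 and 7 without mixed A replicates 1, 2 and 3. It was 23, 24 and 18 without mixed B replicates 1, 2 and 3. Of the 13 named genes 0 kept the call in every run. In Lis1 ko/+ 0 genes were called by limma (183 at unadjusted p under 0.05), and 1 without Lis1 ko/+ replicate 1.

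In Ndel1 ko/+ at P0 476 genes were called, 168 higher and 308 lower. Synapse genes were higher (4 of 28 rose, 5 adjusted over the list alone, camera adjusted p = 0.0101, and adjusted p = 1 with an estimated correlation). Nrgn was at 1.16 ± 0.17, Syn2 at 0.81 ± 0.10 and Gria3 at 0.51 ± 0.09. Endothelium genes were lower (2 of 16 fell, 4 adjusted over the list alone, camera adjusted p = 0.0344, and adjusted p = 1 with an estimated correlation). The efflux pump Abcb1a was at -0.99 ± 0.19 and the tight junction gene Cldn5 at -0.69 ± 0.10. Meninges genes were lower too (0 of 15 fell, 4 adjusted over the list alone, camera adjusted p = 0.0497, and adjusted p = 1 with an estimated correlation). Choroid plexus genes Clic6 (-1.56 ± 0.40), Folr1 (-1.49 ± 0.34) and Aqp1 (-1.32 ± 0.27) fell, as did Alas2 of haem synthesis in red blood cells (-1.41 ± 0.26), von Willebrand factor, Vwf (-1.34 ± 0.21), the ciliary tektin Tekt2 (-1.73 ± 0.19) and the progenitor factor Pax6 (-0.82 ± 0.14). Rpgrip1 (2.35 ± 0.19), the immediate early gene Egr3 (1.82 ± 0.28), corticotropin-releasing hormone, Crh (1.64 ± 0.25), the sterol enzyme Msmo1 (1.04 ± 0.22) and Xbp1 (0.69 ± 0.11) rose. Ndel1 fell (-0.48 ± 0.09, adjusted p = 0.0099 by limma), a call lost without Ndel1 ko/+ replicate 3 or mixed B replicate 3. The count was 280, 223 and 191 without Ndel1 ko/+ replicates 1, 2 and 3 and 211 and 203 without mixed B replicates 2 and 3. Of the 47 named genes 20 kept the call in every run. All 3 arrays of this group had an actin 3' to 5' difference between 0.391 and 0.431, above that of mixed A (0.154 to 0.205) and mixed B (0.277 to 0.358).

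In Ndel1 ko/cko at P0 99 genes were called, 16 higher and 83 lower. Astrocyte genes were lower (4 of 16 fell, 6 adjusted over the list alone, camera adjusted p = 0.00179, and adjusted p = 0.856 with an estimated correlation): Aqp4 (-1.01 ± 0.18), Apoe (-0.75 ± 0.13), Mlc1 (-0.68 ± 0.11) and the glutamate transporter Slc1a3 (-0.56 ± 0.08). The choroid plexus score was lower in the 3 arrays (5.673, 6.34 and 6.51) than in mixed A (6.666 to 6.957) and mixed B (6.724 to 7.027). Lhx8, a factor of basal forebrain cholinergic neurons (-2.55 ± 0.46), Zic1 (-1.57 ± 0.26), Hap1 (-1.45 ± 0.23) and Tekt2 (-1.39 ± 0.19) fell. So did calretinin, Calb2 (-1.02 ± 0.21), the guidance cue Ntn1 (-1.04 ± 0.17) and Cldn5 (-0.78 ± 0.10). Ntn1 is among the 50 genes nearest Ndel1. The intermediate progenitor factor Eomes (0.76 ± 0.17), the condensin subunit Ncapg2 (0.90 ± 0.15) and Draxin (0.67 ± 0.14) rose. Ndel1 itself was at -0.26 ± 0.09 (adjusted p = 0.579, limma), so that the target does not check the label here. The count was 0 and 21 without Ndel1 ko/cko replicates 1 and 3, and 65 without mixed A replicate 3. It was 35, 59 and 38 without mixed B replicates 1, 2 and 3. Of the 25 named genes 0 kept the call in every run. Against mixed B alone, the wild type on the same side, 183 genes were higher and 249 lower. There 16 lists were called, 0 with an estimated correlation, an alternative chosen after seeing the data, with choroid plexus at a median of -0.59 (adjusted p = 5.98e-06). The actin difference was 0.385 to 0.449, the Gapdh 3' to 5' difference 0.060 to 0.104, above mixed A (-0.083 to -0.047) and mixed B (-0.193 to -0.046), and 1 of the 3 arrays held Xist.

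In Dcx ko/Y at P0 3 genes were called, all lower: Dcx (-7.64 ± 0.17, again a lower bound on the loss, with the mutant mean under the filter), Vwf (-1.32 ± 0.21) and Cldn5 (-0.77 ± 0.10). The count was 7, 1 and 1 without Dcx ko/Y replicates 1, 2 and 3 and 1 and 1 without mixed B replicates 2 and 3. Endothelium genes were lower (1 of 16 fell, camera adjusted p = 0.00516, and adjusted p = 1 with an estimated correlation). So were cell cycle genes (0 of 35 fell, median -0.33, camera adjusted p = 0.00156, and adjusted p = 1 with an estimated correlation) and meninges genes (0 of 15 fell, 1 adjusted over the list alone, camera adjusted p = 0.0311, and adjusted p = 1 with an estimated correlation). In the inbred background Ywhae (-2.92 ± 0.06) fell in 14-3-3 epsilon ko/ko, and the mast cell proteases Cpa3 (1.45 ± 0.21) and Cma1 (1.32 ± 0.17) rose. The count of 3 was 6 without inbred wild type replicate 2. In these mutants 10 lists were called, with 0 members called in each and adjusted p of 0.523 to 0.696 with an estimated correlation. Cell cycle (median 0.05), radial glia (0.08), deep-layer (0.10) and upper-layer (0.08) neurons, axon guidance (0.05) and sterol biosynthesis (0.08) were higher. Astrocytes were lower (median -0.17, 4 of 16 fell adjusted over the list alone). Microglia genes (0 of 13 fell, 1 adjusted over the list alone, camera adjusted p = 0.00048) were lower. So were choroid plexus genes (median -0.70, camera adjusted p = 0.000745). Hypoxia genes were higher (0 of 18 rose, 1 adjusted over the list alone, camera adjusted p = 0.00048). In the libraries labelled inbred Ndel1 ko/+, whose Ndel1 goes against the label, 30 genes were called, 23 higher, among them the striatal phosphodiesterase Pde10a (0.81 ± 0.14) and Wsb1 (0.75 ± 0.16), with Fam50a lower (-0.47 ± 0.10). Hypothalamus genes were higher there (0 of 6 rose, 2 adjusted over the list alone, camera adjusted p = 0.0125, and adjusted p = 0.67 with an estimated correlation). The count was 63, 1 and 1 without inbred Ndel1 ko/+ replicates 1, 2 and 3 and 2 and 4 without inbred wild type replicates 1 and 2.

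At P14 777 genes were called in Lis1 ko/cko, 433 higher and 344 lower, and 0 lists by camera. Against mixed A alone, the wild type on the same side, the balance turned, with 706 higher and 1003 lower. The choroid plexus score was lower in all 3 arrays (5.27 to 5.475) than in mixed A (6.111 to 6.328) but overlapped mixed B (5.364 to 6.166), and replicates 1 and 2 stood apart on the second principal component (values below). The list tests against it, an alternative chosen after seeing the data, called 4 lists, and 0 with an estimated correlation. The glucocorticoid-induced Fkbp5 (1.84 ± 0.26), metallothionein Mt2 (1.40 ± 0.22), Lhx8 (1.78 ± 0.28) and the cell cycle inhibitor Cdkn1a (1.15 ± 0.18) rose. Of 17 astrocyte genes 2 rose, 3 adjusted over the list alone, with Gfap at 1.36 ± 0.21 and Gjb6 at 0.84 ± 0.17. Of 14 microglia genes 2 rose, the complement genes C1qc (1.22 ± 0.18) and C1qb (0.71 ± 0.19), and of the interferon list H2-D1 (0.66 ± 0.11) and H2-K1 (0.43 ± 0.11) rose. Transthyretin, Ttr, a product of the choroid plexus, fell (-4.38 ± 0.90, with a mean of 8.61 ± 1.4 SD against 13.35 ± 0.16 in mixed A and 12.62 ± 1.1 in mixed B). Of 26 cell cycle genes 5 fell and 0 rose, 5 and 1 adjusted over the list alone (camera adjusted p = 0.329), among them Mki67 (-1.16 ± 0.23), Top2a (-0.91 ± 0.17) and Cdk1 (-0.71 ± 0.14). Of 16 myelin genes Ugt8a, an enzyme of galactolipid synthesis (-0.79 ± 0.15), and Olig2 (-0.64 ± 0.16) fell, as did Fabp7 (-0.92 ± 0.15), Neurod1 (-0.84 ± 0.11) and the immediate early genes Egr2 (-1.80 ± 0.42) and Fos (-0.94 ± 0.24). The unfolded protein response genes went both ways, with Xbp1 at -0.81 ± 0.15 and Herpud1 at 0.58 ± 0.11. The count was 17, 18 and 1896 without Lis1 ko/cko replicates 1, 2 and 3 and 500, 281 and 228 without mixed A replicates 1, 2 and 3. Of the 51 named genes 2 kept the call in every run. Fkbp5 and Cdkn1a lost it without Lis1 ko/cko replicate 1.

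The other mutants had fewer calls at P14. In Ndel1 ko/cko 11 genes were called, among them Gdpd3 (-2.14 ± 0.27), the G protein subunit Gnb1 (-1.15 ± 0.05), the astrocyte gene Ntsr2 (-0.77 ± 0.07) and Ndel1 (-0.36 ± 0.06), which fell, and Hps1 (1.35 ± 0.16) and Lancl2 (0.53 ± 0.06), which rose. The count was 7 without mixed B replicate 2. Ndel1 lost its call in 5 of the 9 runs that left out 1 array. Of the 10 named genes 7 kept the call in every run. In mix-labelled Ndel1 ko/+, whose Ndel1 goes against the label, 14 genes were called, with Pcdhb9 at -2.76 ± 0.47, Lars2 at -1.24 ± 0.24, Fabp7 at -0.80 ± 0.15 and Wwox at 1.40 ± 0.20. Astrocyte genes were higher there (0 of 17 rose, 4 adjusted over the list alone, camera adjusted p = 0.0129, and adjusted p = 1 with an estimated correlation). The count was 2, 1 and 1 without mix-labelled Ndel1 ko/+ replicates 1, 2 and 3, and 2 and 0 without mixed A replicates 2 and 3. It was 6 and 7 without mixed B replicates 1 and 3. Against the inbred wild type, an alternative chosen after seeing the data, 0 genes were called by limma (1068 at unadjusted p under 0.05). In Lis1 ko/+ 0 genes were called by limma (194 at unadjusted p under 0.05), and 1 without Lis1 ko/+ replicate 1. In Ndel1 ko/+ 0 were called (128), and 3 without mixed B replicate 2, and Ndel1 was at -0.35 ± 0.06 (adjusted p = 0.343).

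**Figure D5:**
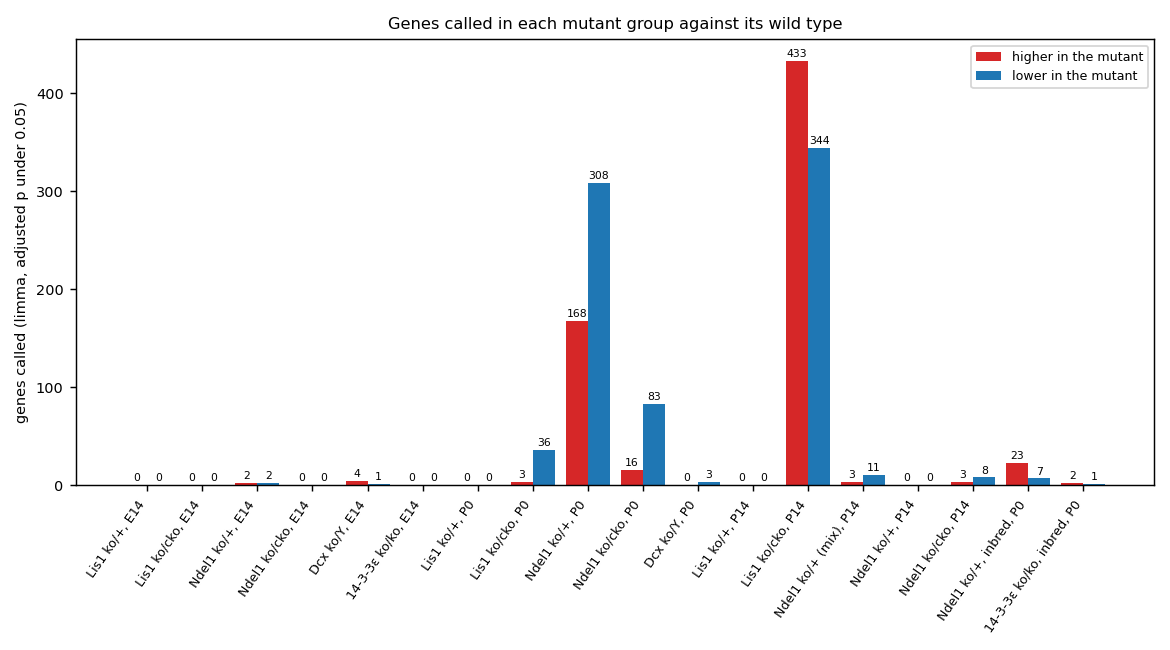
Number of genes called by limma (adjusted p under 0.05) in each mutant group against its wild type, higher (red) and lower (blue) in the mutant, with n = 3 arrays per group. The count was 777 in Lis1 ko/cko at P14 and 476 in Ndel1 ko/+ at P0, and 0 in 7 of the 18 groups.

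The conditional over null genotype was compared with the heterozygote of the same gene, so that no wild type enters. At P0 1076 genes differed between Ndel1 ko/cko and Ndel1 ko/+, 698 higher and 378 lower, and 454 higher and 461 lower with quantile normalization over all arrays. Ndel1 itself was higher in ko/cko (9.56 ± 0.06) than in ko/+ (9.33 ± 0.07), so the target goes against the dose in the labels. The Gapdh 3' to 5' difference, a sign of RNA integrity, parted these groups (0.060 to 0.104 in ko/cko, -0.071 to 0.002 in ko/+), and 1 ko/cko array held Xist. Genes of intermediate progenitors rose (8 of 13, 9 adjusted over the list alone, camera adjusted p = 3.5e-06, and adjusted p = 0.071 with an estimated correlation). Eomes was at 1.36 ± 0.17, Insm1 at 0.97 ± 0.18 and Neurog2 at 0.89 ± 0.26. Of cell cycle genes 9 of 35 rose, 12 adjusted over the list alone (camera adjusted p = 3.5e-06, and adjusted p = 0.45 with an estimated correlation). Mcm7 was at 0.82 ± 0.11. Of radial glia genes 7 of 22 rose, 8 adjusted over the list alone (camera adjusted p = 0.0398, and adjusted p = 0.488 with an estimated correlation). Pax6 was at 0.61 ± 0.14. Of synapse genes 4 of 28 fell, 5 adjusted over the list alone (camera adjusted p = 5.86e-05). Nrgn was at -1.03 ± 0.17. Of astrocyte genes 6 of 16 fell (camera adjusted p = 5.82e-05). Aqp4 was at -0.87 ± 0.18. Of striatum genes 3 of 11 fell and 0 rose, 4 and 1 adjusted over the list alone (camera adjusted p = 0.0311). Penk was at -0.66 ± 0.18. These last 3 lists had adjusted p = 0.311 with an estimated correlation. Hypoxia genes were also called higher and microglia genes lower. Rpgrip1 (-3.14 ± 0.19), Gpc5 (-1.57 ± 0.22) and Crh (-1.46 ± 0.25) were lower, and Gnb1 (1.26 ± 0.19) was higher. The count was 494, 569 and 502 without Ndel1 ko/cko replicates 1, 2 and 3 and 505, 568 and 509 without Ndel1 ko/+ replicates 1, 2 and 3. Of the 61 named genes 30 kept the call in every run.

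Between Lis1 ko/cko and Lis1 ko/+ 67 genes differed at P0, 18 higher and 49 lower. Striatum genes were lower (2 of 11 fell, 4 adjusted over the list alone, camera adjusted p = 0.000281, and adjusted p = 0.038 with an estimated correlation). Penk was at -0.80 ± 0.18 and Rarb at -0.64 ± 0.15. Nxph2 (-1.15 ± 0.17), P2ry12 (-1.10 ± 0.25) and somatostatin, Sst (-0.41 ± 0.08), were lower too. Choroid plexus genes were higher (0 of 11 rose, 1 adjusted over the list alone, median 0.60, camera adjusted p = 0.000281, and adjusted p = 0.556 with an estimated correlation). The LIS1 list and meninges genes were also called higher and GABAergic genes lower. The count was 32 and 3 without Lis1 ko/cko replicates 1 and 2 and 4 without Lis1 ko/+ replicate 3. At P14 986 genes differed, 634 higher and 352 lower, and 529 higher and 693 lower with quantile normalization over all arrays. Replicates 1 and 2 of ko/cko stood apart from replicate 3 on the second principal component (-31.169 and -27.932 against -4.08), and the choroid plexus score was lower in all 3 ko/cko arrays (5.27 to 5.475) than in ko/+ (5.83 to 6.096). Of 16 myelin genes 7 fell, 9 adjusted over the list alone (camera adjusted p = 9.45e-06). Mobp was at -0.75 ± 0.18 and Mog at -0.67 ± 0.17. Of 16 immediate early genes 5 fell and 1 rose (camera adjusted p = 0.00123). Egr2 was at -1.61 ± 0.42 and Arc at -1.13 ± 0.30. Of 14 microglia genes 6 rose and 0 fell, 6 and 1 adjusted over the list alone (camera adjusted p = 0.00248). C1qc was at 1.37 ± 0.18 and Cd68 at 1.02 ± 0.21. Of 15 meninges genes 5 rose, 8 adjusted over the list alone (camera adjusted p = 0.00111). Ogn was at 1.10 ± 0.29. For each of these lists at P14 adjusted p = 0.554 with an estimated correlation. Stk25 (2.57 ± 0.17) and Fkbp5 (1.41 ± 0.26) rose, and Ttr fell (-4.52 ± 0.90). At P14 the count was 27, 30 and 2675 without Lis1 ko/cko replicates 1, 2 and 3 and 1662, 355 and 312 without Lis1 ko/+ replicates 1, 2 and 3.

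At E14 15 genes differed between the libraries labelled Ndel1 ko/cko, whose Ndel1 goes against the label, and Ndel1 ko/+, among them Rpgrip1 (-3.71 ± 0.11), the long non-coding RNA Rmst (-3.43 ± 0.44), Tmem267 (2.95 ± 0.46) and Ndel1 (0.37 ± 0.07). The count was 8, 9 and 8 without Ndel1 ko/cko replicates 1, 2 and 3 and 9, 4 and 8 without Ndel1 ko/+ replicates 1, 2 and 3. Xist separates these groups. Without the 6 arrays of low region score, none of which is in these groups but which share the estimate of the spread, 204 genes were called, an alternative chosen after seeing the data. Between the Lis1 genotypes 5 genes differed at E14, with Zfp33b at 1.01 ± 0.17, Vps52 at 0.85 ± 0.11 and Pign at -0.68 ± 0.09. The count was 1132, 3 and 3 without Lis1 ko/cko replicates 1, 2 and 3 and 9 and 3 without Lis1 ko/+ replicates 1 and 2, and 931 without the 6 arrays of low region score. At P14 38 genes differed between the Ndel1 genotypes, with Zfp874a at 2.24 ± 0.40, Kcnj9 at 1.65 ± 0.24, Gdpd3 at -1.90 ± 0.27 and Gnb1 at -1.07 ± 0.05. The count was 18, 23 and 16 without Ndel1 ko/+ replicates 1, 2 and 3. Immediate early genes were lower there (1 of 16 fell, 5 adjusted over the list alone, camera adjusted p = 8.59e-05). So were myelin genes (0 of 16 fell, 1 adjusted over the list alone, camera adjusted p = 0.000524). Meninges genes were lower too (0 of 15 fell, median -0.26, camera adjusted p = 0.00153). Endothelium genes were also lower (0 of 16 fell, 1 adjusted over the list alone, camera adjusted p = 0.0017). For each of these lists adjusted p = 0.613 with an estimated correlation. Ndel1 averaged 10.00 ± 0.13 in ko/cko and 10.01 ± 0.03 in ko/+.

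Whether a mutation acted differently between ages or backgrounds was tested as an interaction. The effect of Lis1 ko/cko differed between P0 and E14 in 18 genes, 17 lower and 1 higher at P0, with Cck at -0.85 ± 0.18, the synaptic gene Cplx1 at -0.45 ± 0.09 and the imprinted gene Peg3 at 1.24 ± 0.24. At E14 2 of the 3 Lis1 ko/cko arrays and 2 of the 3 mixed A arrays are among those of low region score. Axon guidance genes (0 of 31, camera adjusted p = 0.02) and the LIS1 list (0 of 40, camera adjusted p = 0.0274) had a higher effect at P0. Both had adjusted p = 0.581 with an estimated correlation. The effect of Ndel1 ko/cko, where the Ndel1 of the E14 libraries goes against their label and all 3 hold Xist, differed in 26 genes, 24 lower and 2 higher, with Zic4 at -2.15 ± 0.43, Hap1 at -1.78 ± 0.36, Calb2 at -1.43 ± 0.27 and Slc1a3 at -0.74 ± 0.15. Of 17 astrocyte genes 1 was lower, 3 adjusted over the list alone (camera adjusted p = 0.000608, and adjusted p = 0.979 with an estimated correlation). The effect of Ndel1 ko/+ at P0 differed between the inbred and the unstated background in 31 genes, 23 lower and 8 higher in the inbred, with Nrgn at -1.58 ± 0.19, Rpgrip1 at -2.77 ± 0.51, Gpc5 at -1.72 ± 0.29, Gnb1 at 1.15 ± 0.22 and Ndel1 at 0.63 ± 0.11, where the inbred libraries go against their label. Of 29 synapse genes 1 was lower, 8 adjusted over the list alone (camera adjusted p = 0.000414, and adjusted p = 1 with an estimated correlation), and cell cycle and endothelium genes were called higher. Against mixed A alone the background gave 1034 higher and 977 lower. The Lis1 count was 219, 212 and 0 without Lis1 ko/cko at E14 replicates 1, 2 and 3, and 0, 2 and 51 without Lis1 ko/cko at P0 replicates 1, 2 and 3. It was 9 without mixed A at E14 replicate 3 and 9 and 10 without mixed B at E14 replicates 1 and 2. It was 68, 37 and 0 without mixed A at P0 replicates 1, 2 and 3, and 9 without mixed B at P0 replicate 3. The Ndel1 ko/cko count was 2, 17 and 6 without Ndel1 ko/cko at E14 replicates 1, 2 and 3, and 4 and 13 without Ndel1 ko/cko at P0 replicates 1 and 3. It was 14, 14 and 9 without mixed B at E14 replicates 1, 2 and 3, and 17 without mixed A at P0 replicate 1. It was 11, 15 and 11 without mixed B at P0 replicates 1, 2 and 3. The background count was 15 and 20 without Ndel1 ko/+ replicates 1 and 3, and 20 without inbred Ndel1 ko/+ replicate 2. It was 56 and 8 without inbred wild type replicates 1 and 3, and 50 without mixed A replicate 1.

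No gene was called in every mutant: 0 were shared by the 4 mutants at E14, by the 4 at P0 or by the 2 at P14 (limma). At E14 this was fixed, since 3 of the 4 mutants had 0 calls. At P0 Dcx ko/Y and inbred 14-3-3 epsilon ko/ko had 3 calls each, their own target among them. These counts thus leave open whether the mutants act alike. At P0 Lis1 ko/cko and Ndel1 ko/cko shared Dop1b (0.55 ± 0.09 in Lis1 ko/cko), where independent lists would share 0.00408 genes higher and 0.254 lower. Ndel1 ko/cko and Dcx ko/Y shared Cldn5 (-0.78 ± 0.10 and -0.77 ± 0.10), where independent lists would share 0.0211. Shared controls are not allowed for in these values. The covariance of the log2 changes of Lis1 ko/cko and Ndel1 ko/cko was -0.00812 at P0, against 0.0051 in unchanged groups simulated against the shared controls, and -0.0384 at P14, against 0.00451. With Lis1 ko/cko against mixed A and Ndel1 ko/cko against mixed B, each the wild type on its own side, the sign turned, with 0.00423 at P0 and 0.0101 at P14. In the reverse assignment these were -0.0779 and -0.184. That of Ndel1 ko/cko and Dcx ko/Y at P0 was 0.023, against 0.00512, and with the controls split it was negative both ways (-0.00437 and -0.00699). That of Lis1 ko/cko and Dcx ko/Y was -0.0203, against 0.00509, and -0.00664 and -0.0914 with the controls split. At E14 the sign changed with the control in all 6 pairs, with 0.00206 for Lis1 ko/cko and Dcx ko/Y and 0.00356 and -0.032 with the controls split. With the controls split, Lis1 ko/cko against mixed A and Ndel1 ko/cko against mixed B shared 9 genes at P0 and 0 at P14, and the reverse assignment shared 61 and 53, while Ndel1 ko/cko and Dcx ko/Y shared 1 and 43. Lis1 ko/cko and inbred 14-3-3 epsilon ko/ko at P0, which share no control, shared 0 genes and had a covariance of 0.012, and 0.0128 and 0.0113 with mixed A or mixed B alone as the control of Lis1 ko/cko. The other pairs without a shared control, also with 0 shared genes, had a covariance of 0.00892 for Ndel1 ko/cko with inbred 14-3-3 epsilon ko/ko (0.00965 and 0.00819 with mixed A or mixed B alone) and -0.00308 for Dcx ko/Y with it (-0.00235 and -0.00381).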

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

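The test that asks for groups on both sides of the first component, the test of genotype for the low region score and the splits within ages or backgrounds were chosen only after the result was seen, while the other tests here were written before. Single arrays were not tested for their distance from the others of their group of 3, and the results here were taken up because an effect differs between groups or a sample goes against its label.

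The effect of Lis1 ko/cko differed between P0 and E14 in 18 genes. They include, with the difference in log2 units, Ptrhd1 (-0.92), Chchd6 (-0.91), Higd1a (-0.90), Stn1 (-0.88), Cck (-0.85), Hpca (-0.85), Tsr2 (-0.83), Dhps (-0.68), Cplx1 (-0.45) and Peg3 (1.24). That of Ndel1 ko/cko differed in 26 genes, with Zic4 (-2.15), Hap1 (-1.78), Fam183b (-1.46), Tekt2 (-1.45), Calb2 (-1.43), Ecel1 (-1.28), Wasf3 (-1.07), Ttyh1 (-0.99), Slc1a3 (-0.74), Slco5a1 (0.82) and Zfp995 (1.32). The effect of Ndel1 ko/+ differed between backgrounds in 31 genes, with Rpgrip1 (-2.77), Gpc5 (-1.72), Nrgn (-1.58), Bpnt1 (-1.34), Sstr4 (-1.34), Ddn (-1.25), Met (-1.24), Mblac2 (-1.21), Ptk2b (-1.09), Ttc5 (0.59), Ndel1 (0.63), Prkab1 (0.67), Usp11 (0.70), Ip6k2 (0.80), Gnb1 (1.15) and Ccl27a (1.41). In the library labelled Dcx ko/Y replicate 2 at P0 Xist was 11.27.

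Arrays of a comparison were also split in other ways, and the splits that called as many genes as the real one were counted, the real one included. Where the real count is 0 every split reaches it, so that 100 of 100 is fixed and tests nothing. For development from E14 to P0 this was 1 of 100 (6411 real, highest other 0), and for P0 to P14 1 of 100 (7256, 0). For the inbred against the mixed wild types it was 4 of 100 at P0 (118, 2774) and 3 of 100 at P14 (30, 4737). At E14 it was 1 of 100 for Ndel1 ko/+ (4, 0) and 1 of 100 for Dcx ko/Y (5, 0), and 100 of 100 for Lis1 ko/+ (0, 32), Lis1 ko/cko (0, 0), Ndel1 ko/cko (0, 1) and the group labelled 14-3-3 epsilon ko/ko (0, 20). At P0 it was 3 of 100 for Lis1 ko/cko (39, 2049), 3 of 100 for Ndel1 ko/+ (476, 788), 4 of 100 for Ndel1 ko/cko (99, 2201), 2 of 100 for Dcx ko/Y (3, 2292) and 100 of 100 for Lis1 ko/+ (0, 1839). At P14 it was 5 of 100 for Lis1 ko/cko (777, 5575), a share not under 0.05. It was 4 of 100 for mix-labelled Ndel1 ko/+ (14, 5299), 1 of 100 for Ndel1 ko/cko (11, 8), and 100 of 100 for Lis1 ko/+ (0, 5412) and Ndel1 ko/+ (0, 5602). For the interactions it was 8 of 100 for Lis1 by age (18, 5138), 4 of 100 for Ndel1 by age (26, 2496) and 13 of 100 for Ndel1 by background (31, 2120). These 3 values and those of development tell nothing about chance, since such splits move arrays between ages or backgrounds and the difference between those enters. With each array kept within its age it was 3 of 100 for Lis1 (18, 619) and 4 of 100 for Ndel1 (26, 458), and with each kept within inbred or other background 7 of 100 for Ndel1 ko/+ (31, 1992), where chance is not excluded. The highest of these splits each keep all P0 arrays of mixed A or of mixed B together. Interactions aside, in the comparisons with both mixed wild types at P0 or P14 each highest other split of 1839 genes or more keeps all arrays of mixed B or of mixed A together. Those at E14 that call 32 and 20 follow the low region score. These splits, and the highest within ages or backgrounds, point to structure of the samples. Real groups at P0 and P14 never mix the sides of the first component, as other splits can. A share there, under 0.05 or not, thus does not decide on chance.

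With 10 splits the number is too few for a share under 0.05. The real split alone reached its count, 1 of 10, in inbred development (9225, highest other 0), mixed A against B at E14 (8, 0), P0 (3386, 4) and P14 (6478, 1), inbred Ndel1 ko/+ (30, 0) and inbred 14-3-3 epsilon ko/ko (3, 1). The same held, at 1 of 10, for the Ndel1 dose at E14 (15, 0), P0 (1076, 1) and P14 (38, 8) and the Lis1 dose at P0 (67, 3). For the Lis1 dose it was 3 of 10 at E14 (5, 2891), where the highest split follows the low region score, and 2 of 10 at P14 (986, 2330), where the highest split sets ko/cko replicates 1 and 2 with ko/+ replicate 1 against the rest.

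The first pattern weighed is the 2 sides at P0 and P14. Effects of single probe sets, such as the 3' bias of degraded RNA, might part them: probe-set pairs of the same gene correlated at 0.37 in mixed A against B at P14, between the bounds set, which leaves such effects open. The actin 3' to 5' difference goes against 3' bias at P14, where it overlapped between the sides (0.627 to 0.717 and 0.497 to 0.956), while at P0 it parted them. By the earlier prediction a difference of background appears at E14 too, but the slope of E14 on P0 differences was 0.15. This cannot exclude background, which may act differently at each age, and the genes were chosen by their calls at P0. The slope of P14 on P0 was 0.83, and 2374 of 2446 genes called at both had the same direction. Since 0 of 18 groups had arrays on both sides, a batch of processing cannot be parted from group.

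The second pattern is the low region score of 6 arrays at E14. Hox genes and the other members of the list shared 3 low arrays, where 1.5 would by chance, which leaves open whether the dissection ended further forward or the tissue differs. Genotype as the only cause is excluded, since 4 groups held both low and other arrays, but a partial effect of genotype was not tested. The third pattern is mix-labelled Ndel1 ko/+ at P14, which could be of inbred background: its median shift along the inbred differences was 0.08, which by the letter of the earlier prediction met it. The inbred wild type itself showed none (0.00), Lis1 ko/+ gave -0.01, and a rule added after seeing the values makes the test void. Of its 14 called genes 10 are shared in direction with the 30 of inbred against mixed wild type, but both comparisons use the same mixed wild types, so the background stays open.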

How the results depend on the processing

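The region and Ywhae alternatives, the inbred wild type for mix-labelled Ndel1 ko/+ and the same-side list tests were chosen after seeing the data, while the others were set before. Signs of named genes were kept except for the values named below, and counts moved with the wild type used as control, with the arrays of low region score and with single arrays. The cause of each move was not tested, except where fewer genes or arrays enter. Of the values of named genes, quantile normalization over all arrays left 958 calls as they were and weakened 58, no filter 967 and 51, all 78 arrays in 1 fit 815 and 163, and leave-one-out 6889 and 1713. Where a stricter filter drops a gene, no value is given. Dim genes near the filter of 5.253 log2 units limit what can be called.

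Counts that moved by more than 1.5 times, main to alternative, were these. Without a filter: mixed A against B at E14 (8 to 13), inbred against mixed wild type at P0 (118 to 59), Lis1 ko/cko at P0 (39 to 23) and Lis1 by age (18 to 11). With the stricter filter, which tests fewer genes: mixed A against B at E14 (8 to 1), inbred Ndel1 ko/+ at P0 (30 to 63) and inbred 14-3-3 epsilon ko/ko at P0 (3 to 1). Then came Lis1 dose at E14 (5 to 3) and Lis1 by age (18 to 56). With all 78 arrays in 1 fit: mixed A against B at E14 (8 to 58), Lis1 ko/cko at E14 (0 to 1) and Ndel1 ko/+ at E14 (4 to 12). Then came Ndel1 ko/cko at E14 (0 to 2), Lis1 ko/+ at P0 (0 to 1) and Lis1 ko/cko at P0 (39 to 96). Next were Dcx ko/Y at P0 (3 to 5), mix-labelled Ndel1 ko/+ at P14 (14 to 25) and inbred Ndel1 ko/+ at P0 (30 to 89). After these were inbred 14-3-3 epsilon ko/ko at P0 (3 to 13), Lis1 dose at E14 (5 to 98), Ndel1 dose at E14 (15 to 27) and Lis1 dose at P0 (67 to 143). With quantile normalization over all arrays: Lis1 dose at E14 (5 to 3), Lis1 by age (18 to 9) and Ndel1 by background (31 to 49). With every probe set tested: inbred against mixed wild type at P0 (118 to 209), inbred against mixed wild type at P14 (30 to 127) and Lis1 ko/+ at P0 (0 to 1). Then came Ndel1 ko/+ at P0 (476 to 721), Ndel1 ko/cko at P0 (99 to 340) and Lis1 ko/+ at P14 (0 to 1). Next were Ndel1 ko/cko at P14 (11 to 17), inbred Ndel1 ko/+ at P0 (30 to 61) and Lis1 dose at P14 (986 to 1679). After these were Lis1 by age (18 to 11) and Ndel1 by age (26 to 278).

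The wild type used as control moved the counts as follows, with the main count given above or in the report. With mixed A alone at E14: Ndel1 ko/+ 48, Ndel1 ko/cko 8, Dcx ko/Y 11 and 14-3-3 epsilon ko/ko 1. Then at P0 came inbred against mixed wild type 288, Lis1 ko/cko 278, Ndel1 ko/+ 5054, Ndel1 ko/cko 3983 and Dcx ko/Y 3529. Next at P14 were inbred against mixed wild type 517, Lis1 ko/+ 1, Lis1 ko/cko 1709 and mix-labelled Ndel1 ko/+ 119. After these were Ndel1 ko/+ 6431, Ndel1 ko/cko 6494 and genes shared by mutants 454, also at P14. Further were Lis1 by age 792, Ndel1 by age 2777 and Ndel1 by background 2011. With mixed B alone at E14: Lis1 ko/+ 6, Lis1 ko/cko 207, Ndel1 ko/cko 2, Dcx ko/Y 12 and 14-3-3 epsilon ko/ko 3. Then at P0 came inbred against mixed wild type 5353, Lis1 ko/+ 2438, Lis1 ko/cko 3862, Ndel1 ko/+ 1115 and Ndel1 ko/cko 432. Next at P14 were inbred against mixed wild type 5978, Lis1 ko/+ 6466, Lis1 ko/cko 7336, mix-labelled Ndel1 ko/+ 6467 and Ndel1 ko/cko 22. Further were Lis1 by age 2063, Ndel1 by age 68, Ndel1 by background 230 and genes shared by mutants at E14 2 and at P14 9. With the mean of mixed A and mixed B, which asks less than both, development from E14 to P0 had 9666. Inbred against mixed wild type had 3847 at P0 and 3127 at P14. Next at E14 were Lis1 ko/cko 10, Ndel1 ko/+ 27, Ndel1 ko/cko 6 and Dcx ko/Y 11. Then at P0 came Lis1 ko/+ 286, Lis1 ko/cko 2356, Ndel1 ko/+ 3767, Ndel1 ko/cko 2050 and Dcx ko/Y 950. After these at P14 were Lis1 ko/+ 3120, Lis1 ko/cko 5777, mix-labelled Ndel1 ko/+ 3561, Ndel1 ko/+ 2858 and Ndel1 ko/cko 3184. Further were Lis1 by age 1630, Ndel1 by age 1166, Ndel1 by background 662 and genes shared by mutants at P14 119. With the inbred wild type alone: Ndel1 ko/+ at P14 (0 to 5792) and mix-labelled Ndel1 ko/+ at P14 (14 to 0). With Lis1 against mixed B and the others against mixed A: genes shared by mutants at P14 (0 to 53).

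With the region score as a covariate at E14: mixed A against B at E14 (8 to 26). Without the 6 arrays of low region score, which leaves 1 Lis1 ko/cko and 1 mixed A array assumed to vary like the other groups: mixed A against B at E14 (8 to 14), Lis1 ko/+ at E14 (0 to 3) and Lis1 ko/cko at E14 (0 to 418). Then came Ndel1 ko/+ at E14 (4 to 19), Lis1 dose at E14 (5 to 931) and Ndel1 dose at E14 (15 to 204). Without the 2 arrays that keep Ywhae: 14-3-3 epsilon ko/ko at E14 (0 to 1). With an estimated correlation fewer lists were called. The number fell in development from E14 to P0 (8 to 3), from P0 to P14 (10 to 2) and inbred development (12 to 2). It fell in the Lis1 dose at P0 (5 to 1). From the number in brackets it went to 0 in all that follow. These were mixed A against B at E14 (8) and P0 (1) and inbred against mixed wild type at P14 (1). Then came Ndel1 ko/+ at E14 (5) and P0 (3), Lis1 ko/cko (1), Ndel1 ko/cko (1) and Dcx ko/Y (3) at P0. Next were mix-labelled Ndel1 ko/+ at P14 (1) and, at P0, inbred Ndel1 ko/+ (1) and inbred 14-3-3 epsilon ko/ko (10). After these were the Lis1 dose at E14 (4) and P14 (4) and the Ndel1 dose at E14 (8), P0 (8) and P14 (4). Further were Lis1 by age (2), Ndel1 by age (1) and Ndel1 by background (3).

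The replicate numbers in the labels do not pair the samples. With them as a block the count for mixed A against B at E14 went from 8 to 5, and the block moved no other count by more than 1.5 times. The mean correlation of arrays with the same number was -0.035 at E14, -0.007 at P0 and 0.014 at P14, and 9 of 24, 7 of 30 and 12 of 24 arrays correlated best with their own number.

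The balance of higher and lower calls turned in several comparisons. With quantile normalization it went from 1903 higher and 4508 lower to 3339 and 2540 for development from E14 to P0, from 634 and 352 to 529 and 693 for the Lis1 dose at P14, from 698 and 378 to 454 and 461 for the Ndel1 dose at P0, and from 433 and 344 to 478 and 532 for Lis1 ko/cko at P14. Against mixed A alone that last one was 706 and 1003. Against mixed B alone Lis1 ko/cko at P0 went from 3 and 36 to 2073 and 1789. With the stricter filter inbred development went from 4882 and 4343 to 3097 and 3391. With 1 alternative or leave-one-out run or more it also turned for mixed A against B at E14, inbred against mixed wild type at P0 and P14, inbred 14-3-3 epsilon ko/ko at P0, mix-labelled Ndel1 ko/+ and Ndel1 ko/cko at P14, the Lis1 and Ndel1 doses at E14, the Ndel1 dose at P14 and Ndel1 by background. The covariances of mutants that changed sign with the control are in the report. Reversed signs of named genes were few. With mixed B alone Pafah1b1 was 0.06 in Lis1 ko/+ and 0.13 in Lis1 ko/cko at P0. Against the inbred wild type in mix-labelled Ndel1 ko/+ at P14, Slc38a9 was -0.06, Rfx7 0.12, Nim1k 0.05 and Dstn 0.02. In the Ndel1 dose at P14 Ndel1 was 0.01 without Ndel1 ko/+ replicate 3 and 0.06 without Ndel1 ko/cko replicate 3, and it ranged from -0.07 to 0.06 in leave-one-out runs.

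In leave-one-out runs, which use fewer arrays, the lowest and highest counts follow. Mixed A against B had 1 to 46 at E14, 2232 to 3336 at P0 and 5552 to 5969 at P14. Inbred against mixed wild type had 7 to 180 at P0 and 0 to 27 at P14. Next were development from E14 to P0 5929 to 6605, from P0 to P14 6910 to 7396 and inbred development 8710 to 8896. After these were Lis1 dose at E14 3 to 1132, Ndel1 dose at E14 4 to 9, Lis1 dose at P0 3 to 64 and Ndel1 dose at P0 494 to 569. Further were Lis1 dose at P14 27 to 2675, Ndel1 dose at P14 16 to 32, Lis1 by age 0 to 219 and Ndel1 by age 2 to 26. Ndel1 by background had 8 to 56. Lis1 ko/+ had 0 to 1 at each age. Lis1 ko/cko had 0 to 382 at E14, 1 to 59 at P0 and 17 to 1896 at P14. Ndel1 ko/+ had 2 to 4, 191 to 514 and 0 to 3 at these ages. Ndel1 ko/cko had 0 to 5, 0 to 104 and 7 to 13. Dcx ko/Y had 2 to 6 at E14 and 1 to 7 at P0. The rest were 14-3-3 epsilon ko/ko at E14 0 to 0 and inbred at P0 3 to 6. Then came inbred Ndel1 ko/+ at P0 1 to 63 and mix-labelled Ndel1 ko/+ at P14 0 to 14. Genes shared by mutants were 0 to 0 at E14 and P0 and 0 to 1 at P14.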

Other observations

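The tests of neighbours were written before their result was seen, with same-side controls chosen after the 2 sides were seen, while the genes of the first paragraph were chosen only after the result was seen. Several single genes differed greatly between groups of the same age. Rpgrip1 averaged 10.39 in Ndel1 ko/+ at E14 against 6.95 and 6.92 in mixed A and B, and 9.63 at P0 against 7.25 and 7.32, while Ndel1 ko/cko held it at 6.68 and 6.49. In the inbred background at P0 it averaged 5.91 in wild type and 5.49 in Ndel1 ko/+. Gnb1 averaged 10.71 in Ndel1 ko/cko at P14 against 11.91 and 11.80.

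Lists were also called where few members were. Between mixed A and mixed B at E14 8 lists were called, with cell cycle higher (median 0.42, camera adjusted p = 1.17e-08, and adjusted p = 0.742 with an estimated correlation) and meninges lower (median -0.77, camera adjusted p = 0.00697, and adjusted p = 0.802 with an estimated correlation), the pattern of the low region arrays. In the Lis1 dose at E14 4 lists were called and in the Ndel1 dose at E14 8, none with an estimated correlation (0 and 0 lists). Against the wild type on the same side, an alternative chosen after seeing the data, sterol biosynthesis genes were higher in Ndel1 ko/+ at P0 (7 of 16 rose, adjusted p = 2.56e-07, and adjusted p = 0.365 with an estimated correlation). In Lis1 ko/cko at P14 8 of 26 cell cycle genes and 9 of 16 myelin genes fell there, with adjusted p = 0.615 with an estimated correlation.

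A hypothesis was that genes near the targeted locus carry alleles of the strain in which the mutation was made, and that the 50 nearest genes hold more changes than others (one-sided Fisher exact test, adjusted over the comparisons). At P0 and P14 the Lis1 mutants were tested here against mixed A alone and the Ndel1 and Dcx mutants against mixed B alone, each the wild type on the same side, and at E14 against both mixed wild types, so the counts at E14 and at the later ages have unlike controls. Inbred 14-3-3 epsilon ko/ko was tested against inbred wild type. In Ndel1 ko/cko at P0 15 of 50 neighbours had an unadjusted p under 0.05 (30% against 17.9% elsewhere, 3 called, Ntn1 among them, adjusted p = 0.206, exact). In Lis1 ko/cko the adjusted exact p was 0.985 at E14 (3 of 50), 0.357 at P0 (15 of 50, 30% against 22.4%, 4 called) and 0.357 at P14 (19 of 50, 38% against 29.4%, 12 called). In Ndel1 ko/+ it was 1 at E14 (0 of 50) and 0.985 at P0 (12 of 50, 24% against 24.5%, 4 called), in Dcx ko/Y at P0 0.991 and in inbred 14-3-3 epsilon ko/ko at P0 0.985. None of these tests decides for or against such alleles.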
